A study of Drosophila melanogaster with 18 samples.

How the data were processed

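Poly(A) RNA of the male excretory tract was sequenced at day 7, day 28 and day 56 of adult life, in 6 libraries per age. Per the labels' protocols, each tube held 15 tracts, libraries were made from 200 ng of RNA with a directional kit, and paired reads of 60 bp were collected to at least 20 M (M, 1e6) per library. Libraries A to C of an age were dissected on its first date and D to F on its second, so that the 6 dates are nested in the ages and no model can hold both date and age as free terms.

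The authors trimmed reads with cutadapt 4.1, quantified transcripts with Salmon 1.9.0 and used DESeq2 1.40.2, per the submitters' processing notes. The genome build and the transcript set used for that step are not given in the sources used here. Each deposited file lists, per transcript, an estimated count of reads, which need not be a whole number, and a TPM value, with lengths beside them, per the file headers. The deposited estimated counts are not normalised, while the deposited TPM values are scaled by the authors' quantifier for transcript length and for the sum over the library.

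Transcript identifiers were matched to the Ensembl release 115 annotation of the BDGP6.54 assembly, which is not known to be the authors' own. Of 32965 transcripts in the files, 10 had no match there, and these held at most 0.00476% of the estimated reads of a library. Estimated counts were summed over the 16299 genes and rounded to whole numbers. Totals per library lay between 20.2 M and 25.4 M estimated reads. A gene with no reads in the 6 libraries of an age was given a floor of 3 counts over that age, which covers counting error only. Coordinates are those of the annotation named above, counted from 1.

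The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust estimation, TMM factors and the filterByExpr filter by age, which left 12310 genes. All 18 libraries entered 1 fit with age as the factor, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Day 56 and day 28 were each compared with day 7, and day 56 with day 28. A further contrast compared the change per day over the 21 days from day 7 to day 28 with that over the 28 days from day 28 to day 56. CPM values are counts per 1e6 reads with TMM-adjusted library sizes. Errors of log2 fold changes are the estimate divided by the square root of the quasi-likelihood F.

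Gene lists for pathways of the tract and for cell types of this and neighbouring tissues were written before the data were examined, as were the tests, the first set of alternatives and the rule for naming genes. The 42 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The same test with an estimated correlation and the fry test stand beside it. Members were also counted with p-values adjusted over the list alone. Summed CPM of a list were compared between ages with a two-sided exact permutation test on log2(sum + 1) over the 924 splits of 12 libraries, whose smallest p is 0.00216. Of the gene symbols on the lists, Gss1 had no match and Ald, Dl and Peb were ambiguous, so that these 4 were left out.

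The naming rule took, for day 56 against day 7, the 10 largest rises and 10 largest falls among genes past the threshold with a change of at least 2-fold, a mean of at least 5 CPM in the higher age and no overlap between the libraries of the ages. It took 5 and 5 for each of the other comparisons, 5 genes for the difference in rate, and up to 4 members per list with the smallest adjusted p. It also allowed every tested member of the tubule proton pump and acid-base lists. The genes in the text are a part of those the rule allows, and that part was picked after the values were seen. Members without values of their own that are named as background to a list count were picked in the same way.

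The edgeR step was tested on simulated counts drawn from the real means and library sizes with 200 genes changed by known folds. For day 56 against day 7, over 12060 genes, it called 18.8% of genes changed 1.5-fold, 65.6% of those changed 2-fold and 75.4% of those changed 4-fold, with 4 false calls. The list step called 1 of 1 changed list and 0 others. The simulated genes were drawn independently of each other, so this cannot show how often lists whose genes move together are falsely called. In the real data the estimated correlation was 0.23 in the oxidative phosphorylation list and 0.784 in the V-ATPase tubule set. Counts of 45 pairs of libraries of the same age were compared by chi-square, and no pair came near sampling noise (at least 48.0 per gene). No library was therefore taken as a copy of another, and each entered the tests as a replicate. The comparison cannot show that the tubes are independent, and the labels do not say whether they came from separate cultures.

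The alternatives were DESeq2 1.42.0, RLE, upper-quartile and library-size-only factors, no low-count filter, a filter of 5 CPM in 6 libraries, a transcript-length offset, only the ages compared, a block for the library letter, an additive term for first or second date, limma voom with date as a random block, counts summed per date, each set of dates alone, limma on log2(TPM + 1) and log2(TPM + 0.1), stricter thresholds, and leaving out each library in turn. Levels of testis, accessory gland and midgut markers as covariates, and fits without libraries under or over a level of testis markers, were added after seeing the data, as was a fit with flight and general muscle levels as covariates. Tables were made with pandas 2.3.3 and numpy 2.4.6 and plots with matplotlib 3.10.9.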

Results

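RNA of the excretory tract of male Drosophila melanogaster was sequenced at 3 ages, day 7, day 28 and day 56, with 6 libraries per age named A to F. The tract holds the Malpighian tubules, which are the renal tubules of the fly, together with hindgut and rectal ampulla. The series concerns acidification of body fluids in ageing, and its design text asks how the tract comes to fail with age. Libraries held between 20.2 M and 25.4 M estimated reads (M, 1e6). The labels do not say whether the tubes of an age came from separate cultures of flies, so the p-values measure the spread between these tubes. In what follows, ± after a level in CPM is the SD over the 6 libraries of an age, ± after a log2 fold change is its SE, and p-values are from edgeR or, for lists, from camera, both after Benjamini-Hochberg adjustment.

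Markers of neighbouring male tissues varied between libraries. Testis markers, such as the sperm tail and protamine genes, summed to 748 ± 948 CPM at day 7, 721 ± 563 at day 28 and 291 ± 263 at day 56, with single libraries between 3.20 and 2384 CPM. At day 7 they summed to 135, 3.20 and 7.73 CPM in libraries A, B and C of the first dissection date and to 2384, 1317 and 639.9 in D, E and F of the second. The 2 dates of day 7 differed in 2849 genes, and in 1566 of these (55%) the level tracked the testis sum within ages (correlation over 0.8). Of all 12310 genes tested, 2500 tracked it. The day 7 libraries enter both measures, and their testis sum itself differed by date. Part of the 55% is therefore built in. The 2 dates of day 28 and those of day 56 differed in 0 genes by edgeR, with 1681 and 607 genes at an unadjusted p under 0.05. Accessory gland and ejaculatory duct markers, which encode seminal fluid proteins, summed to 6946 ± 5068 CPM at day 7, 1974 ± 2223 at day 28 and 200.0 ± 274 at day 56. The fall from day 7 to day 56 was larger than the spread between libraries (exact permutation p = 0.00216, the smallest possible, and 0.0114 after adjustment over the lists). Midgut digestive enzymes summed to 11409 ± 7190, 8577 ± 5195 and 11845 ± 6359 CPM. The first principal component of log2 CPM, the axis of largest spread between libraries, held 73.4% of the variance, and the ages overlapped on it. At day 7 it ran from −184 in B to 154 in D, the libraries with the lowest and highest testis sums. The second held 11.6%. On it day 56 (20.2 to 62.2) lay apart from day 7 (−94.9 to 17.1), and day 28 overlapped both.

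**Figure D1:**
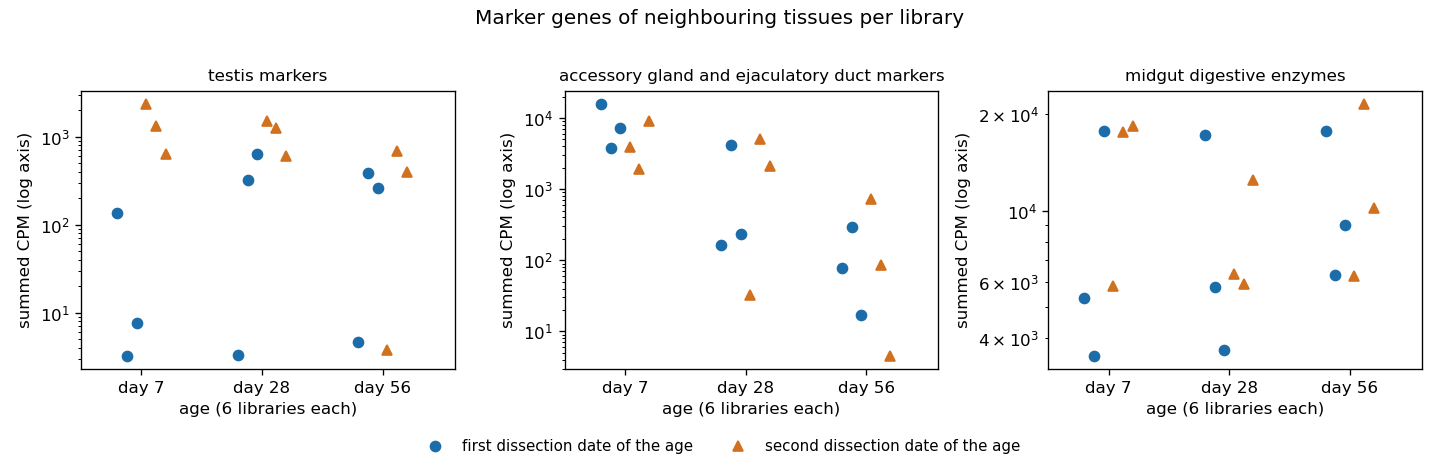
Summed CPM of testis, accessory gland and midgut marker genes in each of the 18 libraries, on log axes, by age and by dissection date (circles first date, triangles second date). Testis sums ranged from 3.20 to 2384 CPM, and mean accessory gland sums went from 6946 CPM at day 7 to 200.0 CPM at day 56.

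Day 56 was compared with day 7 to ask how the tract of old males differs from that of young ones. Antimicrobial peptide genes rose together, in 12 of 14 members, among them DptA, which encodes the antibacterial peptide diptericin A and went from 10.7 ± 6.88 to 397 ± 232 CPM (log2 fold change 5.21 ± 0.53, adjusted p = 8.16e-06). Genes of oxidative phosphorylation, the mitochondrial route of ATP synthesis, fell together, in 68 of 90 members. PPO2, which encodes a prophenoloxidase of the melanisation reaction made by crystal cells of the blood, fell from 41.1 ± 16.6 to 0.173 ± 0.192 CPM (log2 fold change −7.82 ± 0.77, adjusted p = 6.98e-06). Of the 12310 genes tested, 1771 rose and 1426 fell, and 351 and 460 of these changed at least 2-fold. Of the 42 gene lists, 22 passed camera, while 0 did with an estimated correlation (3 at an unadjusted p under 0.05) and 20 by fry.

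SPH93, a serine protease homologue, rose from 0.0322 ± 0.0788 to 9.19 ± 5.10 CPM (log2 fold change 7.83 ± 1.10, adjusted p = 1.21e-04). IBIN, a short peptide gene induced by infection, rose by 7.33 ± 0.87 on the log2 scale (adjusted p = 2.93e-05). Def, which encodes defensin, rose by 6.75 ± 1.15 (adjusted p = 6.18e-04), Dro, which encodes drosocin, by 6.66 ± 0.81 (3.63e-05), and AttC, which encodes an attacin, by 5.50 ± 0.74 (8.41e-05). AttB rose by 5.57 ± 0.67 (3.41e-05), a value shared in an uncertain way with its near-identical neighbour AttA. CG14125, the largest rise that meets the naming rule (8.68 ± 2.43, adjusted p = 0.0159), stood at 45.3 ± 69.7 CPM at day 56, an SD above the mean.

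The antimicrobial peptide list summed to 103 ± 39.1 CPM at day 7, 216 ± 88.6 at day 28 and 1528 ± 524 at day 56. Its median log2 fold change was 4.92, with 13 of 14 members past the threshold adjusted over the list alone, and the list passed camera (adjusted p = 2.73e-12; adjusted p = 0.106 with an estimated correlation). Over the 4 pairs of a day 56 date with a day 7 date the median lay between 4.62 and 5.30. Toll pathway and Bomanin genes, which include short secreted peptides made under Toll control, rose in 16 of 25 members (17 adjusted over the list alone; camera adjusted p = 6.22e-09, and adjusted p = 0.449 with an estimated correlation). They included BomS3 (2.81 ± 0.28, adjusted p = 8.02e-06) and Dso1 (2.45 ± 0.24, 5.54e-06). Peptidoglycan recognition proteins and the IMD pathway, which sense bacterial wall fragments, rose in 9 of 19 members (9 adjusted over the list alone; camera adjusted p = 7.84e-06, and adjusted p = 0.449 with an estimated correlation). Day 56 C was the highest of the 6 day 56 libraries in 13 of these 19 members, and the list passed camera also without it (adjusted p = 2.34e-06). PGRP-SB1 rose by 2.67 ± 0.22 (adjusted p = 1.11e-06) and PGRP-LB, an amidase that breaks down peptidoglycan, by 1.21 ± 0.15 (3.55e-05). In the JAK-STAT list, 6 of 11 members rose (6 adjusted over the list alone; camera adjusted p = 0.0188, and adjusted p = 0.486 with an estimated correlation). They included upd3, a cytokine, at 1.29 ± 0.695 and 10.5 ± 9.99 CPM (log2 fold change 3.01 ± 0.73, adjusted p = 0.00698). Day 56 C had 30.5 CPM of upd3 and the 5 others a median of 6.14, and the log2 fold change was 2.26 without it (adjusted p = 0.0207). Another was Socs36E, an inhibitor of the same pathway (1.79 ± 0.37, 0.00263). The fat body, a main source of antimicrobial peptides in flies, had markers summing to 2028 ± 526 CPM at day 7 and 1549 ± 301 at day 56 (exact permutation p = 0.0844).

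**Figure D2:**
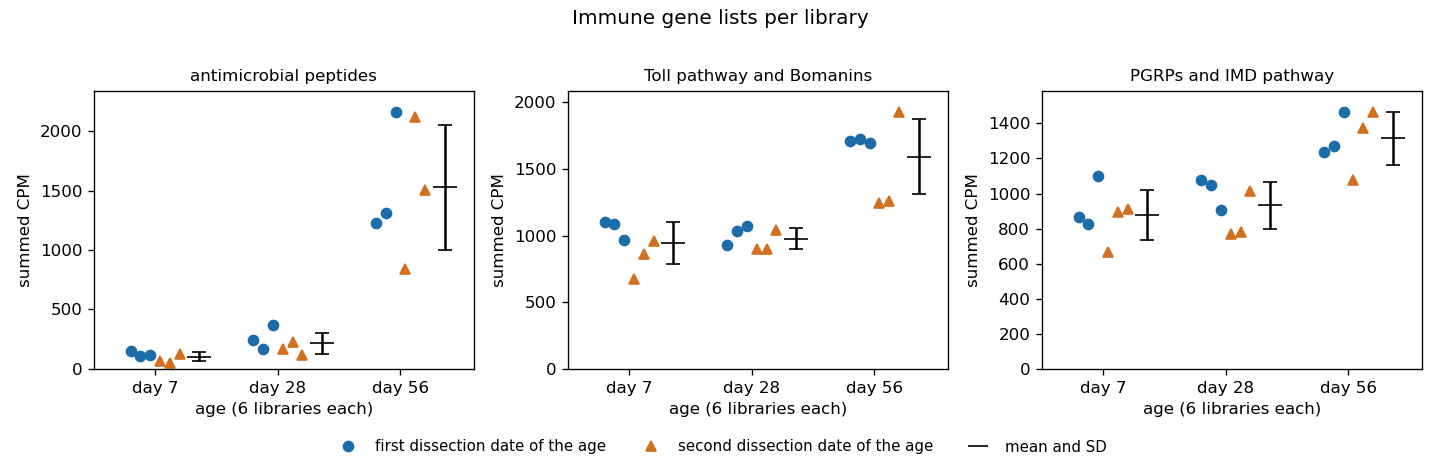
Summed CPM of 3 immune gene lists in each library by age, with the mean and SD of the 6 libraries of each age beside the points (circles first dissection date, triangles second). The antimicrobial peptide sum went from 103 ± 39.1 CPM at day 7 to 1528 ± 524 at day 56.

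Oxidative phosphorylation genes summed to 19126 ± 1600 CPM at day 7, 14772 ± 657 at day 28 and 13005 ± 899 at day 56. The list had a median log2 fold change of −0.59 at day 56 against day 7, with 68 members lower also when adjusted over the list alone, and passed camera (adjusted p = 2.98e-37; adjusted p = 0.0613 with an estimated correlation). The median lay between −0.64 and −0.45 over the 4 pairs of dates. ND-MWFE and ND-19, subunits of complex I of the respiratory chain, fell by 0.63 ± 0.06 (adjusted p = 4.59e-06) and by 0.59 ± 0.05 (3.12e-06) on the log2 scale. Of the 22 members that did not pass, 20 tracked the testis marker sum, and the median level of the 22 was 4.51 CPM, against 144 CPM for the 68. The median log2 fold change of the 22 was −1.27, against −0.55 for the 68. Members that track testis thus enter the list median and camera. The 4 genes listed as markers of flight muscle, a tissue rich in mitochondria, summed to 57.4 ± 34.7 CPM at day 7, 7.06 ± 3.11 at day 28 and 8.79 ± 5.01 at day 56 (exact permutation p = 0.0108 for day 56 against day 7, and 0.0325 after adjustment over the lists). Most of each sum came from Act79B, at 54.3 ± 34.3, 5.15 ± 2.56 and 5.85 ± 3.66 CPM. The sums thus mainly follow this 1 gene, and their fall does not show a fall of flight muscle RNA. Of the 4 flight muscle markers 3 fell (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0854). In the TCA cycle list, the mitochondrial pathway that feeds the respiratory chain, 21 of 21 members fell (21 adjusted over the list alone), with a median of −0.47 and camera adjusted p = 2.58e-19 (adjusted p = 0.106 with an estimated correlation). They included SdhD (−0.52 ± 0.05, adjusted p = 8.58e-06), which serves both pathways, and ScsbetaA (−0.54 ± 0.06, 1.10e-05), a subunit of succinyl-CoA synthetase. Mitochondrial ribosomal protein genes fell in 29 of 72 members (38 adjusted over the list alone; camera adjusted p = 1.53e-12, and adjusted p = 0.486 with an estimated correlation). Mitochondrially encoded genes, a separate list, fell in 3 of 13 members (0 adjusted over the list alone). Camera adjusted p was 0.00773 (0.578 with an estimated correlation). Their summed CPM was 32191 ± 8659 at day 7 and 19203 ± 8406.5 at day 56, and the difference did not pass (exact permutation p = 0.0584). A fall of this sum is thus neither shown nor excluded. In glycolysis, 6 of 13 members fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 0.00745, and adjusted p = 0.486 with an estimated correlation). The member that rose was Ldh, lactate dehydrogenase, at 57.7 ± 12.9 and 213 ± 111 CPM (log2 fold change 1.89 ± 0.30, adjusted p = 3.83e-04), while Gapdh1 fell by 0.46 ± 0.07 (2.38e-04).

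**Figure D3:**
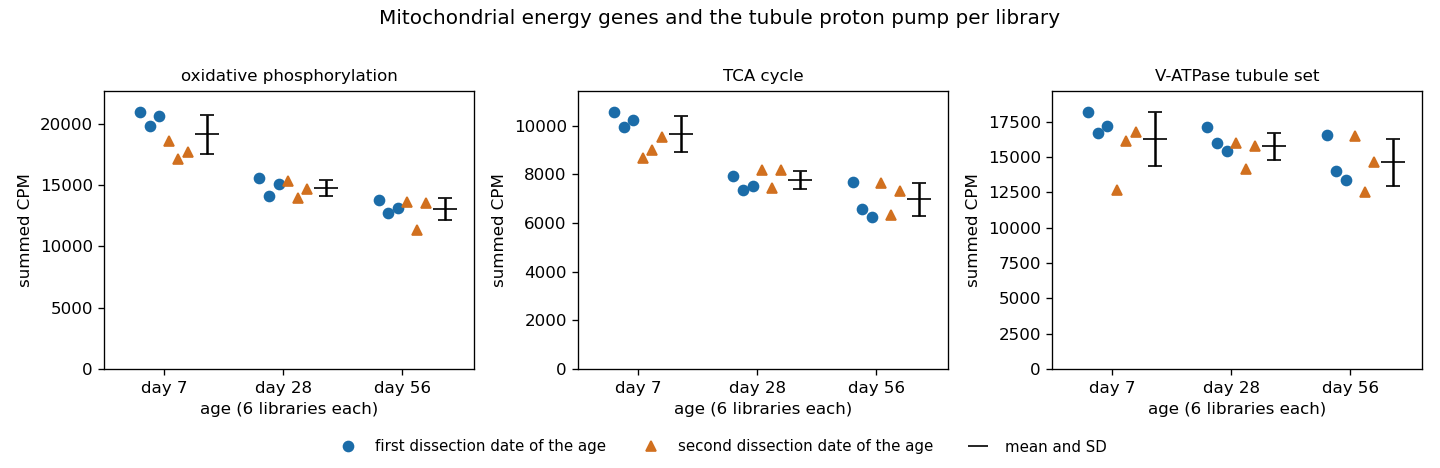
Summed CPM of oxidative phosphorylation, TCA cycle and tubule V-ATPase genes in each library by age, with the mean and SD of the 6 libraries of each age beside the points (circles first dissection date, triangles second). Oxidative phosphorylation sums went from 19126 ± 1600 CPM at day 7 to 13005 ± 899 at day 56, and V-ATPase sums were 16286 ± 1916 and 14621 ± 1657 CPM.

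The V-ATPase is the proton pump that energises fluid secretion by the tubules. Of the 14 tested genes of its tubule set, 3 fell (3 adjusted over the list alone), and the 11 others did not pass. Vha13, Vha36-1 and Vha14-1, all subunits of its peripheral part, had log2 fold changes of −0.42 ± 0.10 (adjusted p = 0.00665), −0.37 ± 0.10 (0.0107) and −0.24 ± 0.07 (0.0188). The median of the set was −0.14, from −0.20 with RLE factors to −0.02 with library size only, while the median of all genes was −0.04, −0.11 and 0.07 under the same scalings. Against the first day 7 date the median of the set was −0.22 and −0.24 in the day 56 dates, with 3 genes lower in each. Against the second it was −0.05 and −0.05, with 0 lower by edgeR (0 also unadjusted). Camera called the set lower (adjusted p = 0.003, and 0.578 with an estimated correlation), and the difference in its summed CPM between the ages did not pass (exact permutation p = 0.158). On log2(TPM + 1) Vha14-1 turned to 0.02 (adjusted p = 0.891), and in the second dates alone none of these 3 genes passed (adjusted p = 0.189, 0.259 and 0.341). Acid-base transport genes, which include carbonic anhydrases and sodium-proton exchangers, fell in 4 of 22 members (6 lower and 2 higher adjusted over the list alone). They included CAH5 (−1.93 ± 0.45, adjusted p = 0.00539) and CAH9 (−0.50 ± 0.11, 0.00287), both carbonic anhydrases, and Nha1 (−0.55 ± 0.11, 0.0019), a member of the NHA antiporter family. The list median was −0.34 and camera adjusted p was 0.0248 (0.0645 without day 56 C, and adjusted p = 0.486 with an estimated correlation), with a fry adjusted p of 0.0236. Its summed CPM went from 2748 ± 269 at day 7 to 2245 ± 249 at day 56 (exact permutation p = 0.0152, and 0.0398 after adjustment over the lists). The list median was 0.14 with the testis, accessory gland and midgut levels as covariates.

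Stem cell markers rose in all 3 tested members (3 adjusted over the list alone; camera adjusted p = 0.00369, and adjusted p = 0.449 with an estimated correlation). These were esg, a transcription factor of intestinal and renal stem cells (1.57 ± 0.17, adjusted p = 1.73e-05), Sox100B (1.64 ± 0.34, 0.0027) and pnt (0.81 ± 0.19, 0.00655). Their sum in day 56 C was 163 CPM against at most 106 in the other day 56 libraries. Insulin and FOXO pathway genes rose in 8 of 13 members (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00321, and adjusted p = 0.486 with an estimated correlation). They included InR, the insulin receptor (1.16 ± 0.19, adjusted p = 4.75e-04), and ImpL2, a secreted protein that binds insulin-like peptides (1.71 ± 0.31, 0.00109). Day 56 C had 582 CPM of ImpL2, against a median of 172.5 in the other day 56 libraries. The insulin and FOXO list passed camera also without day 56 C (adjusted p = 0.00108). Heat shock protein genes rose in 10 of 26 members (10 adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.449 with an estimated correlation). Day 56 C was the highest of the day 56 libraries in 16 of these 26 members, and the list passed camera also without it (adjusted p = 0.00123). The members that rose included Hsp22 of the mitochondrial matrix (1.81 ± 0.30, 4.21e-04) and Hsp70Bb (2.69 ± 0.41, 2.55e-04), which shares reads with near-identical copies. Antioxidant enzyme genes fell in 10 of 20 members and rose in 1 (the same counts adjusted over the list alone; camera adjusted p = 0.00231, and adjusted p = 0.486 with an estimated correlation). Sod1 and Sod2, the cytosolic and mitochondrial superoxide dismutases, fell by 0.51 ± 0.08 (3.09e-04) and 0.46 ± 0.06 (8.90e-05), and Irc, an immune-regulated catalase, rose by 0.69 ± 0.10 (1.05e-04).

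Blood cell (haemocyte) markers fell in 7 of 10 members and rose in 1 (7 lower and 2 higher adjusted over the list alone; camera adjusted p = 5.2e-05, and adjusted p = 0.449 with an estimated correlation). PPO1, the other crystal cell prophenoloxidase beside PPO2, changed by −6.93 ± 0.57 on the log2 scale (adjusted p = 1.00e-06), and Pxn, a peroxidase of the extracellular matrix, by −2.23 ± 0.14 (2.36e-07). The member that rose was lz, a transcription factor of crystal cell formation (3.33 ± 0.40, 3.03e-05), at 0.309 ± 0.116 and 3.14 ± 1.03 CPM. In the principal cell list, the main cell type of the tubule, 3 of 12 members rose and 4 fell (the same counts adjusted over the list alone; camera adjusted p = 0.53). Uro, urate oxidase, rose from 362 ± 80.2 to 867 ± 184 CPM (1.26 ± 0.18, 1.36e-04), and Alp4, the alkaline phosphatase of the tubule, fell from 1105 ± 201 to 541 ± 151 CPM (−1.03 ± 0.17, 4.82e-04).

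Seminal fluid genes were among the other large falls. Accessory gland and ejaculatory duct markers fell in 18 of 21 members (20 adjusted over the list alone; camera adjusted p = 7.7e-07, and adjusted p = 0.486 with an estimated correlation). CG43254 stood at 7.34 ± 9.74 CPM at day 7 and had no reads at day 56, at least 348-fold lower against a floor of 3 counts over the 6 libraries (0.0211 CPM). Acp62F, a seminal fluid gene, stood at 13.0 ± 17.0 CPM at day 7 and had 1 read in all of day 56. Sfp60F, another, fell from 784 ± 678 to 6.14 ± 13.3 CPM (log2 fold change −7.00 ± 1.93, adjusted p = 0.0148).

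Between first dates alone 2283 genes differed, between second dates alone 581, with date as a random block in voom 948 and with counts summed per date 2, while with testis, accessory gland and midgut levels as covariates 743 passed the threshold, 719 of them among the 3197, and with flight and general muscle levels 2268, 1820 of them among the 3197. Without libraries under 150, under 100 and over 100 CPM of testis markers the counts were 3155, 1977 and 435, while the share of rises among the 3197 was 55.4%, and 43.6% with RLE factors, 44.9% with DESeq2 and 74.9% with library size only.

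Day 28 was compared with day 7 to ask what had changed by middle age. Tig, which encodes tiggrin, an extracellular matrix ligand of integrins, rose from 52.1 ± 19.3 to 295 ± 74.2 CPM (log2 fold change 2.50 ± 0.24, adjusted p = 4.26e-05). Antdh, a short-chain dehydrogenase first described in the antenna, rose from 17.5 ± 6.79 to 63.9 ± 9.43 CPM (1.87 ± 0.20, 1.29e-04), and stnA, of synaptic vesicle recycling, by 1.88 ± 0.29 (0.00323). PPO1 fell from 49.3 ± 21.1 to 5.40 ± 3.12 CPM (−3.19 ± 0.47, 0.00273) and PPO2 by 3.47 ± 0.62 (0.00537). Oxidative phosphorylation genes fell in 67 of 90 members. With flight and general muscle levels as covariates 45 were lower (66 unadjusted), the list median was −0.40 against −0.36, and the median SE of a member was 0.11 against 0.08. Over all genes tested, 189 rose and 357 fell, 46 and 54 of them at least 2-fold, and 17 of the 42 lists passed camera (1 with an estimated correlation, 9 by fry).

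The oxidative phosphorylation list had a median of −0.36 at day 28 (68 lower adjusted over the list alone), and it passed camera with the preset correlation (adjusted p = 1.81e-41) and with an estimated one (adjusted p = 0.0395). Flight muscle markers fell in 2 of 4 members (3 adjusted over the list alone; camera adjusted p = 0.00685, and adjusted p = 0.323 with an estimated correlation). General muscle markers fell in 3 of 18 (6 adjusted over the list alone; camera adjusted p = 2.13e-05, and adjusted p = 0.551 with an estimated correlation). TCA cycle genes fell in 15 of 21 members (20 adjusted over the list alone; camera adjusted p = 1.03e-22, and adjusted p = 0.0915 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 10 of 72 (13 adjusted over the list alone; camera adjusted p = 1.50e-18, and adjusted p = 0.323 with an estimated correlation). ND-19 fell by 0.35 ± 0.05 (adjusted p = 0.00323) and ScsbetaA by 0.33 ± 0.06 (0.00512). Haemocyte markers fell in 6 of 10 members and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 7.08e-08, and adjusted p = 0.223 with an estimated correlation). Antimicrobial peptide genes rose in 4 of 14 members (8 adjusted over the list alone; camera adjusted p = 1.98e-05, and adjusted p = 0.329 with an estimated correlation), among them Dro (3.17 ± 0.70, 0.0169). Antioxidant enzyme genes fell in 5 of 20 members (9 adjusted over the list alone; camera adjusted p = 2.51e-06, and adjusted p = 0.323 with an estimated correlation). The Toll and Bomanin list (camera adjusted p = 0.629), the V-ATPase tubule set (0.152) and acid-base transport (0.69) did not pass.

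The count of 546 genes was 217 in first dates, 3 in second dates, 18 by voom with date as a random block, 12, 20 and 6 without libraries under 150, under 100 and over 100 CPM of testis markers, 494 with muscle levels as covariates (198 shared), 1394 by DESeq2, and 1630 with library size only, where the share of rises went from 34.6% to 80.7%. It was 329, 336, 312 and 322 without day 7 A, day 7 B, day 28 B and day 28 C, and 881 without day 56 C.

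Day 56 was compared with day 28 to ask what changed later in this span. The largest rises that meet the naming rule include SPH93, the serine protease homologue (log2 fold change 5.07 ± 0.95, adjusted p = 0.00847), IBIN (3.99 ± 0.73, 0.00768) and the attacin gene AttC, which rose from 16.2 ± 8.32 to 210.1 ± 89.9 CPM (3.70 ± 0.68, 0.00816). Hsp70Bb, an inducible chaperone gene with near-identical copies, rose by 2.62 ± 0.41 (0.00281), and Ldh rose to 213 ± 111 CPM (1.79 ± 0.30, 0.00453). PPO1 fell from 5.40 ± 3.12 to 0.394 ± 0.293 CPM (−3.75 ± 0.50, 6.13e-04), and GstD11, a glutathione transferase, by 1.44 ± 0.18 (4.07e-04). Over all genes tested, 171 rose and 119 fell, 80 and 65 of them at least 2-fold. Of the 42 lists, 17 passed camera, 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 9 by fry.

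Toll and Bomanin genes rose in 12 of 25 members (12 adjusted over the list alone; camera adjusted p = 2.47e-18, and adjusted p = 0.171 with an estimated correlation), with BomS3 at 24.9 ± 7.63 and 119 ± 35.0 CPM (2.25 ± 0.28, adjusted p = 3.66e-04). Antimicrobial peptide genes rose in 9 of 14 members (12 adjusted over the list alone; camera adjusted p = 8.37e-18, and adjusted p = 0.0781 with an estimated correlation). Peptidoglycan recognition and IMD genes rose in 7 of 19 (8 adjusted over the list alone; camera adjusted p = 1.05e-09, and adjusted p = 0.171 with an estimated correlation). The stem cell marker esg rose from a mean of 15.8 to 33.3 CPM (adjusted p = 0.00311). Oxidative phosphorylation genes fell in 2 of 90 members (19 adjusted over the list alone; camera adjusted p = 1.58e-17, and adjusted p = 0.171 with an estimated correlation). With flight and general muscle levels as covariates 22 were lower (60 unadjusted), and the list median was −0.22 against −0.19. Acid-base transport genes fell in 2 of 22 members (5 adjusted over the list alone; camera adjusted p = 0.00274, and adjusted p = 0.288 with an estimated correlation). Camera called the V-ATPase tubule set lower (adjusted p = 0.00274, and 0.817 with an estimated correlation), with 0 of 14 members lower. That call was lost without day 28 A (0.106) or day 56 E (0.0569). Camera called general muscle markers higher (adjusted p = 0.00274, and 0.817 with an estimated correlation), with 1 of 18 members higher. Accessory gland and ejaculatory duct markers fell in 10 of 21 members (18 adjusted over the list alone; camera adjusted p = 1.18e-10, and adjusted p = 0.334 with an estimated correlation).

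The count of 290 genes was 13 in first dates, 5 in second dates, 41 by voom with date as a random block, 132 with 3 tissue levels and 686 with muscle levels as covariates (272 shared), 289, 161 and 1 without libraries under 150, under 100 and over 100 CPM of testis markers, and 1039 by DESeq2, and the share of rises, 59%, was 47.2% with RLE factors and 39.6% with DESeq2. It was 443 without day 7 D, and 175, 169, 193, 158 and 167 without day 28 B, E and F and day 56 B and E.

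The change per day was compared between day 7 to 28 and day 28 to 56 to ask which genes had an early or a late course. It differed in 4 genes, all with the larger change in the earlier interval. Tig, the matrix gene above, changed by 2.50 ± 0.24 on the log2 scale by day 28 and stood at 295 ± 74.2 and 307 ± 63.8 CPM at day 28 and day 56 (adjusted p of the difference in rate = 0.00728). The level of yellow-d, a member of the yellow gene family, was 92.7 ± 7.31, 180 ± 22.9 and 190.1 ± 11.9 CPM at the 3 ages (0.00728). The genes CG43134 (0.0194) and CG13215 (0.0252), for which no function is given here, were at 8.02 ± 1.44, 22.2 ± 3.23 and 20.6 ± 4.88 CPM and at 9.40 ± 2.33, 47.4 ± 13.6 and 67.5 ± 13.2 CPM. Antdh missed the threshold (0.0548) and passed it in 7 of the 33 alternatives chosen before the results, 1 of them without day 7 B (0.0019).

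At an unadjusted p under 0.05 the rate differed in 970 genes, DESeq2 called 117, and the dates alone, voom with date as a random block and edgeR with muscle levels as covariates (1376 unadjusted) called 0. The count was 2 without day 7 E or day 28 A, B or D, and the call of CG43134 was lost without day 7 E (adjusted p = 0.05002), day 28 A (0.0619), B (0.0551), D (0.0760) or F (0.0570) or day 56 B (0.0657) or F (0.0976), and that of CG13215 without day 7 A (0.0759), C (0.0655) or E (0.0524), day 28 A (0.0726), B (0.104), C (0.130) or D (0.0760) or day 56 A (0.0578), D (0.0549) or E (0.0530).

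Genes changed at day 28 and at day 56, both against day 7, were compared to ask how far the earlier change is seen in old males. They shared 522 genes, 181 higher and 341 lower at both ages. Independent lists of these sizes share 27.2 and 41.4, a value that leaves out that both comparisons use the same day 7 libraries. With the first day 7 date for day 56 (3459 genes) and the second for day 28 (151 genes), 118 were shared with the same direction. The other way round (3021 and 3111 genes) 619 were. What independent lists of these sizes would share was not computed, so these counts do not show sharing beyond chance. The mitochondrial genes ND-19 and ScsbetaA and the blood cell genes PPO1, PPO2 and Pxn were among those lower at both ages.

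Positions on the reference assembly are as follows for the genes given most weight. DptA lies on chromosome arm 2R from 18865765 to 18866260 on the plus strand, PPO1 on 2R from 17887220 to 17889973 and PPO2 on 2R from 9042261 to 9044709, both on the minus strand. ND-19 lies on 2R from 24664398 to 24665439 on the plus strand, esg on 2L from 15333866 to 15336138 on the plus strand, Nha1 on 2L from 6860905 to 6870389 and Vha13 on 3R from 19643018 to 19644386, both on the minus strand, and Tig on 2L from 6415179 to 6423310 on the minus strand. All are annotated as protein-coding genes.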

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

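The tests of single libraries and of the rate were chosen before the results were seen, while all tests that weigh an explanation below were chosen after.

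Single libraries stood apart from the 5 others of their age, by Dixon's ratio, in 33 of 315 groups (10.5%), where chance gives 5% for normally distributed values. Over the 8904 genes with a mean of at least 5 CPM the share was 9.22% at day 7, 3.95% at day 28 and 13.9% at day 56. The 10.5% lies within that range, so it does not set these groups apart from genes in general. In day 56 C the genes ImpL2 at 582 CPM (median of the others 172.5, given in brackets from here on unless as their highest), Socs36E at 355 (128), upd3 at 30.5 (6.14), Sox100B at 43.4 (19.3), RnrL at 41.3 (15.2) and cora at 583 (318) stood high, as did the summed stem cell markers at 163 (99.4). Of the antimicrobial and immune genes, DptB at 14.3 CPM (3.44), Dro at 3.83 (at most 1.55), IBIN at 0.162 (0.0386) and IM18 at 1.99 (0) stood high in day 7 A, SPH93 at 0.193 (0) in day 7 D and AttC at 383 (191) in day 56 E. Blood cell genes stood high in day 28 F, with PPO1 at 11.5 CPM (4.46) and PPO2 at 7.99 (at most 4.26), and PPO2 stood at 73.0 (32.9) in day 7 C, while lz stood low in day 7 E at 0.0837 (0.356).

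Seminal fluid genes stood high in several libraries. Acp54A1 was at 471 CPM in day 7 C (107), 101 in day 28 E (at most 24.9) and 3.11 in day 56 B (0.136), and Sfp60F at 33.2 in day 56 D (0.0864). Acp62F and Sfp65A were each at 0.0407 CPM in day 56 F (0) and CG42481 at 0.0454 in day 56 C (0), which is 1 read each. CG14125 was at 180.2 CPM in day 28 E (0.322). In day 7 D, InR at 29.2 CPM (52.3), MRP at 338.5 (515) and mt:CoI at 5927 (14090) stood low. Nha1 at 778 CPM in day 7 C (591), Oatp58Da at 388.5 in day 7 A (305), and Sod1 at 532 (459) and Vha36-1 at 518 (428) in day 28 A stood high, and ND-19 stood low in day 56 E at 43.8 (51.7).

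The change per day differed between the 2 intervals, by a test of the difference itself, for Tig (adjusted p = 7.28e-03), yellow-d (7.28e-03), CG43134 (0.0194) and CG13215 (0.0252).

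Antimicrobial peptide genes were higher at day 56 than at day 7. The lowest median log2 fold change over the 4 pairs of dates was 4.62, which argues against a single dissection date as the cause. A larger share of fat body RNA with unchanged expression would raise its markers about as far as the peptides (median 4.92), and the highest of the 9 markers, with 2 SE added, reached 3.80, which argues against it. Fat body RNA carried along in which the peptide genes themselves rose stays open, since a summed marker change of −0.37 (exact permutation p = 0.0844) does not decide it. Age, an infection and gut bacteria stay open as well, and none of these was tested.

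Oxidative phosphorylation genes were lower at day 56 than at day 7, with a median of −0.61 with testis, accessory gland and midgut levels as covariates and at most −0.45 over the 4 pairs of dates, which argues against RNA of these tissues and against a single date as the whole cause. With flight and general muscle levels as covariates the median was −0.64 with 67 of 90 members past the threshold. This argues against RNA that varies with these 2 levels as the whole cause. The flight muscle level came mostly from Act79B (54.3 of 57.4 CPM at day 7), so it need not follow flight muscle as a whole. A smaller share of principal cells with unchanged expression would lower the genes of these cells about as far. The summed list changed by −0.40 ± 0.08 (SE) relative to the summed V-ATPase tubule set and by −0.46 ± 0.10 relative to the summed principal cell markers (exact p = 2.16e-03 for both, the smallest possible). This argues against it as the whole cause only where the reference genes kept their expression. Of the 12 principal cell markers 3 rose and 4 fell, and of the 14 V-ATPase genes 3 fell. Neither sum need therefore follow the share of these cells. Age and a smaller share with changed reference genes stay open. A smaller share as part of the cause cannot be told apart from a change within cells. The mean log2 level of the 75 members of at least 5 CPM, tested first, changed by −0.34 relative to the V-ATPase tubule set (exact p = 0.188). That test decides nothing, because its values differed widely within an age (SD 0.42 at day 7). At day 7 they ran from −3.22 in B to −2.11 in D, the libraries with the lowest and highest testis sums (3.20 and 2384 CPM). The sums were compared after the result of that first test, as were 3 more versions. These gave −0.37 for 85 members of this list and the TCA cycle picked because they were lower (exact p = 2.16e-03). They gave −0.29 for 21 TCA cycle genes (2.16e-03) and 0.14 for 12 principal cell markers (0.0173).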

How the results depend on the processing

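The alternatives that use levels of other-tissue markers were chosen after the results were seen, and the others before. Counts below are of genes for day 56 against day 7, day 28 against day 7, day 56 against day 28 and the rate, which were 3197, 546, 290 and 4. The cause of a difference in these counts was not tested for any alternative, also where fewer libraries or units entered.

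DESeq2 gave 3988, 1394, 1039 and 117, and library size only gave 4639, 1630, 465 and 8. Voom with date as a random block (correlation 0.285) gave 948, 18, 41 and 0 (235 at an unadjusted p under 0.05). Counts summed per date, with 2 units per age, gave 2, 0, 0 and 0, with 1111, 1022 and 536 at an unadjusted p under 0.05 for the last 3. First dates gave 2283, 217, 13 and 0 (1247 unadjusted), and second dates 581, 3, 5 and 0 (695 unadjusted), with 3 libraries per age. Limma on log2(TPM + 1) gave 5628, 2761 and, for the rate, 12, and on log2(TPM + 0.1) 5656, 2828 and 8. No low-count filter gave 192 for day 56 against day 28. An adjusted p under 0.01 gave 1574, 193, 89 and 2. An adjusted p under 0.05 with a change of at least 2-fold gave 811, 100, 145 and 0.

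The 3 tissue levels as covariates gave 743 for day 56 against day 7 and 132 against day 28, flight and general muscle levels gave 2268, 494, 686 and 0 (1376 unadjusted), and the testis level alone gave 7 for the rate. Without libraries under 100 CPM of testis markers, which leaves 4, 5 and 4 per age, the counts were 1977, 20, 161 and 1. Without those over 100 CPM, which leaves 2, 1 and 2, they were 435, 6, 1 and 2, and the lone day 28 library is assumed to vary like the others. Without those under 150 CPM, a bound tried first, they were 3155, 12, 289 and 4.

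Leaving out each library gave 2701 to 3399, 312 to 881, 158 to 443 and 2 to 6 genes. The count for day 28 against day 7 was 329 and 336 without day 7 A and B, 312 and 322 without day 28 B and C and 881 without day 56 C. That for day 56 against day 28 was 443 without day 7 D, 175, 169 and 193 without day 28 B, E and F and 158 and 167 without day 56 B and E. The rate count was 2 without day 7 E or day 28 A, B or D.

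Gene lists past the threshold, 22, 17 and 17 for the 3 pairs of ages, were 0, 1 and 0 with an estimated correlation (3, 5 and 7 unadjusted). By fry they were 9 for day 28 against day 7 and 9 for day 56 against day 28, and second dates gave 9 for day 28 against day 7. Leaving out each library gave 20 to 24, 16 to 22 and 15 to 19. With the library letter as a block the gene counts were 3322, 509, 366 and 3. The 522 shared genes were 118 and 619 with day 7 split by date and 186 at an adjusted p under 0.01.

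Vha14-1 at day 56 against day 7 reversed to 0.0177 on log2(TPM + 1) and on log2(TPM + 0.1). With muscle levels as covariates Act79B, itself on the flight muscle list, reversed to 0.0143 at day 56 and 0.139 at day 28. In second dates the cytochrome P450 list at day 56 against day 7 (camera adjusted p = 0.462, from 0.0155) and the cell cycle list at day 28 against day 7 (0.112, from 0.00685) turned to the other direction without passing. With an estimated correlation both calls with all dates were lost (adjusted p = 0.578 and adjusted p = 0.630). The P450 call was lost without day 7 B (0.0577) or C (0.0997) or day 56 C (0.106), and the cell cycle call without day 7 A (0.0887). For named genes, the alternatives chosen before the results kept direction and side of the threshold in 3640 cases, lost the threshold in 403, passed it anew in 7 and reversed in 2, and those added later gave 499, 215, 4 and 2.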

Other observations

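The tests of list members were chosen before the results were seen, while the tests on other groupings of libraries and on clock genes and the counts for day 56 C were chosen after.

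Members of further lists changed at day 56 against day 7. Purine and urate genes, of the nitrogen waste pathway, rose in 6 of 15 members and fell in 1 (the same counts adjusted over the list alone). Camera adjusted p was 0.052 (0.486 with an estimated correlation) and fry adjusted p 0.00354. Their summed CPM rose from 1926 ± 138 to 2535 ± 225 (exact permutation p = 0.00216, and 0.0114 after adjustment over the lists). Cytosolic ribosomal protein genes fell in 23 of 92 members (22 adjusted over the list alone; camera adjusted p = 5.12e-11, and adjusted p = 0.513 with an estimated correlation), and 8 members were lower with library size only and 79 with DESeq2. Organic solute carriers rose in 2 of 15 members and fell in 4 (3 and 5 adjusted over the list alone; camera adjusted p = 0.174), with Orct at −0.66 ± 0.11 (adjusted p = 4.08e-04) and MRP, a multidrug transporter, at 0.39 ± 0.10 (0.00762). Glutathione transferases rose in 4 of 34 members and fell in 9 (5 and 10 adjusted over the list alone; camera adjusted p = 0.174), with GstD11 at −2.59 ± 0.19 (6.16e-07) and GstD2 at 1.82 ± 0.30 (4.54e-04).

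Other groupings of the same libraries were fitted, 100 per comparison with the real one included. They take libraries as independent, while the libraries of a date share a correlation of 0.285, and the 4 dates of a pair of ages allow only 3 groupings by whole date, too few for a share under 0.05. For day 56 against day 7, 1 of 100 gave as many genes as the real 3197 (highest other 0), and for day 56 against day 28, 1 of 100 gave as many as 290 (highest other 7). Chance is unlikely there only if libraries are taken as independent, which their correlation within dates goes against. Chance between dates is not excluded, and counts summed per date gave 2 genes and 0 (1022 at an unadjusted p under 0.05 for the latter) by edgeR. For day 28 against day 7, 3 of 100 gave at least 546. The highest other, 929, is the split by first and second date, and a random one gave 629. Within first dates 217 genes differed, within second dates 3 and by voom with date as a random block 18, so chance between dates is not excluded. For the rate, 2 of 100 gave at least 4, and the highest other, a random grouping, gave 228. What set that grouping apart was not tested. Chance is not excluded for these 4 genes either.

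Library day 56 C stood apart on the high side in 835 of 8904 genes (9.38%), against at most 189 in any other library. On the low side day 7 D stood apart most often, in 382 genes, and day 56 C in 43. Day 56 C was the highest of the 6 day 56 libraries in 16 of 18 cell cycle genes, 62 of 92 cytosolic and 55 of 72 mitochondrial ribosomal protein genes and 32 of 48 proteasome genes. The same held in 13 of 19 peptidoglycan recognition and IMD genes, 16 of 26 heat shock genes, 3 of 3 stem cell markers and 4 of 4 flight muscle markers.

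The clock gene tim differed between libraries of the same date. It averaged 126 CPM in libraries A and D, 216 in B and E and 409 in C and F, in the same order in all 6 dates (exact within-date p = 1.29e-04). A candidate explanation is the time of day of dissection, which the labels do not give. The clock genes per and vri, which cycle with tim, shared an order between dates with exceptions, with mean ranks of 1.17, 1.83 and 3 for per and 1, 2.17 and 2.83 for vri (larger exact p = 1.67e-03). The 7 other clock genes did not pass (adjusted p from 0.859 to 0.956). The order was noticed first in these data and these 3 genes were picked after their values were seen, while over all genes 2 held a single order in all 6 dates where chance gives 1.58.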
